A study of Homo sapiens with 6 samples.

How the data were processed

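The series holds 6 RNA-seq libraries of HepG2 cells, 3 from cells expressing eGFP and 3 from cells expressing TAF2. Per the labels' protocols, total RNA was made into libraries with an Illumina TruSeq RNA kit and sequenced on a HiSeq3000 in 2 rounds. The authors deposited 1 table of expected counts per gene, with a list of RefSeq transcript accessions per gene and no normalization. RSEM and the genome build hg38 are named in the submitters' processing notes. RSEM divides reads that fit several genes or transcripts by estimated probability, so between 4.18% and 4.45% of the deposited expected counts in a library were not whole numbers. The aligner, the annotation release and whether strand was used in counting are not given in the sources used here. Without strand, reads from overlapping or antisense genes cannot be told apart, and values of closely related paralogs such as the AKR1C, HSPA1 and metallothionein genes are uncertain.

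The table has 26475 genes, of which 17454 had a count in at least 1 library. It has no row for eGFP, and genes of the mitochondrial genome were not analysed here. Whether the TAF2 row includes reads from an introduced TAF2 sequence is not stated, so the measured rise need not equal that of the protein or of the introduced copy. Library columns were matched to samples by their names, and 0 columns of per-sample values were left unused. Genes were placed on GRCh38.p14 by matching their transcript accessions to a RefSeq gene table of that assembly, which gave coordinates for 12735 of the tested genes (98.7%). Sex-linked marker genes were kept in the fit and left out of the gene tables.

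Total counts were 27137862, 22276308 and 25011098 in eGFP replicates 1 to 3 and 24631251, 25420298 and 28024004 in TAF2 replicates 1 to 3. The 28S ribosomal gene RNA28S5 held 0.976% ± 0.259 of counts in eGFP and 0.913% ± 0.0103 in TAF2 libraries (SD, n = 3 each). The 20 highest genes held 12.7% on average in eGFP and 12.0% in TAF2. Replicates of a group differed by more than counting error (chi-square per degree of freedom of 1.98 to 5.91 over genes, against 27.2 to 30.8 between groups), so no library was taken as a copy of another. This test covers counting error only and cannot tell separate cultures from repeat preparations of a culture.

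Expected counts were rounded to whole numbers. Genes were kept by filterByExpr of edgeR 4.0.16 (R 4.3.3), which left 12902, scaled by TMM (factors from 0.9976 to 1.003) and compared with the quasi-likelihood test (glmQLFit, robust, and glmQLFTest) in a model with the group alone. P-values were adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05. CPM were computed on the scaled library sizes. The common dispersion was 0.000758, a biological coefficient of variation of 2.75%, which is small for replicates and lets the test call small differences. Counts were simulated from the means and library sizes of this comparison over 12812 genes. The test called 16 of 50 genes changed by 1.1-fold (32.0%), 40 of 50 at 1.25-fold (80.0%), 45 of 49 at 1.5-fold (91.8%) and 45 of 48 at 2-fold (93.8%). It also called 19 of about 12620 unchanged genes, a larger share of its calls than the 0.05 aimed at. Far fewer genes were changed there than the 5548 called in the data. The adjusted threshold was therefore stricter in the simulation, and these rates may understate those in the data.

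Before the data were examined, the comparison, its test, 42 gene lists, the alternatives and the rule for named genes were written down. The rule names TAF2, the 12 largest rises and the 12 largest falls among called genes with a mean of at least 5 CPM and no overlap between groups, passing over genes without an ordinary symbol, and in each list up to 4 called members with the smallest p. Some genes that the rule names are not reported here. A list with no called member would give up to 2 members by CPM. Of 1162 listed genes 1147 were found, 49 of them under older symbols. Lists of at least 5 tested genes were compared with all other genes by camera (limma 3.58.1) with a preset correlation of 0.01, then with an estimated correlation and with fry, TAF2 itself left out. With an estimated correlation camera also uses fewer degrees of freedom, limited by the 6 libraries, so it can miss lists for that reason alone. Within each list p-values were also adjusted over the list alone.

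Chromosomes were examined after the gene results had been seen. Median log2 fold changes of genes of at least 5 CPM (10257 genes on 23 chromosomes) were compared with 10000 random gene lists of the same size. Bins of 10 Mb with at least 10 genes were treated likewise, and a bin counted as shifted when its median was at least 0.15 from 0 and past the adjusted threshold. Chromosomes 4 and 11 counted as shifted along their whole length. In simulated counts a chromosome lowered by 0.2 was recovered at -0.195, and 0 other chromosomes were past the threshold. Genes were drawn independently there and few on other chromosomes were changed. That 0 therefore does not show how specific the test is in the data, where many genes differed.

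Alternatives were DESeq2 1.42.0 as a test and its size factors within edgeR, upper-quartile scaling, library size alone, library sizes without TAF2 and the 20 highest genes, no filter, at least 1 CPM in 3 libraries, unrounded expected counts, the replicate number as a block, each library left out, limma-voom, and glmTreat against 1.5-fold. Added after seeing the data were fits without the shifted regions, with GC content and transcript length corrected by loess (from GENCODE transcripts, with values for 97.9% of tested genes), and the NRF2 list without the AKR1C genes. Figures were drawn with matplotlib 3.10.9.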

Results

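RNA sequencing measured gene expression in HepG2 cells, a human liver cancer line that keeps many hepatocyte functions. Cells expressing TAF2, a subunit of the general transcription factor TFIID, were set against cells expressing enhanced green fluorescent protein (eGFP), a reporter protein. Each group had 3 libraries made from growing cultures. Total counts per library ranged from 22276308 to 28024004. Log expression correlated across genes at r = 0.994 to 0.9957 between libraries of the same group and at 0.9838 to 0.9851 between libraries of different groups. The first principal component held 64.4% of the variance and separated the groups. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

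TAF2 itself (chromosome 8, 119730774 to 119832841, GRCh38.p14) was higher in every TAF2 library than in any eGFP library. Its level rose from 37.9 ± 2.31 CPM (SD, n = 3) to 48.6 ± 1.37 CPM (SD, n = 3), a 1.28-fold difference with a log2 fold change of 0.36 (SE 0.046, edgeR adjusted p = 1.44e-08). The 3 eGFP libraries held 35.8, 40.4 and 37.5 CPM, and the 3 TAF2 libraries held 50.1, 48.3 and 47.4 CPM. Of the genes past the threshold, 1617 changed by more than TAF2 in absolute log2 fold change, and 596 of these rose. The rise of TAF2 was no longer called when the test asked for a change of more than 1.5-fold.

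**Figure D1:**
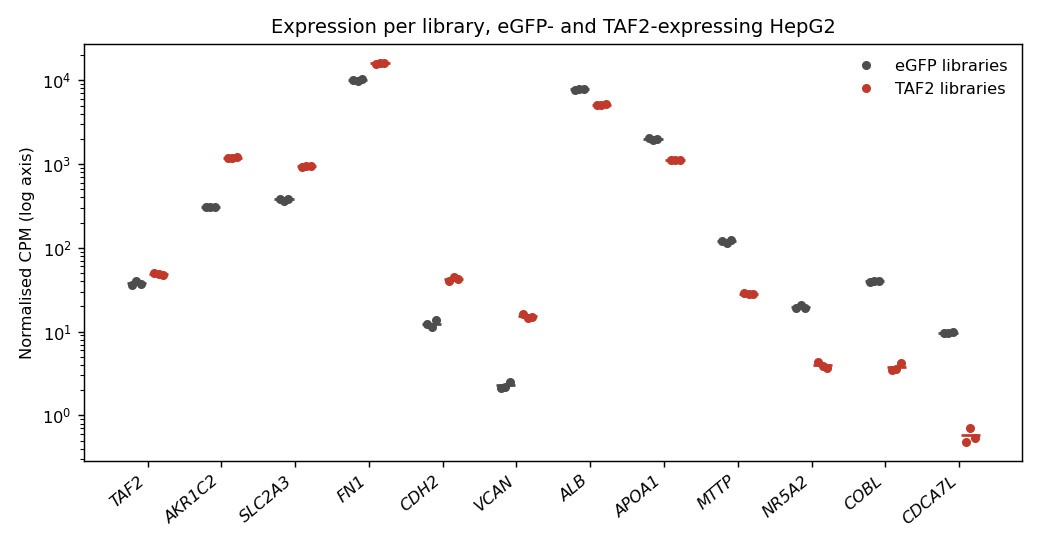
Normalised expression (CPM, log axis) of TAF2 and 11 other named genes in the 3 eGFP libraries (grey) and the 3 TAF2 libraries (red); each point is a library and each bar the group mean. TAF2 moved from 37.9 to 48.6 CPM, while CDCA7L moved from 9.71 to 0.576 CPM.

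Most members of the lists of liver secreted proteins, cholesterol synthesis and fatty acid metabolism fell with TAF2, while most members of the NRF2 antioxidant, heat shock and ribosome biogenesis lists rose. These lists passed the camera test with a preset correlation, and 0 of them held with an estimated correlation, which also lowers the degrees of freedom of the test. At a Benjamini-Hochberg (BH) adjusted p of 0.05, 5548 of 12902 tested genes differed between the groups, 2662 higher and 2886 lower with TAF2. Which direction had more calls depended on the processing, since with upper-quartile scaling 3001 were higher and 2675 lower. Most of these changes were small: the median absolute log2 fold change of the called genes was 0.23, and 4681 of them changed by less than 1.5-fold. An absolute log2 fold change of at least 1 was seen in 381 called genes, 155 higher and 226 lower. A test against a change of 1.5-fold called 373 genes, 153 higher and 220 lower. Among all tested genes, 6528 (50.6%) had no overlap between the 3 TAF2 and the 3 eGFP libraries, against 10% by chance for 3 libraries against 3.

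VCAN, the matrix proteoglycan versican, had the largest rise among called genes with a mean of at least 5 CPM and no overlap between groups. It went from 2.28 ± 0.184 to 15.2 ± 0.815 CPM (SD, n = 3 each), a log2 fold change of 2.73 (SE 0.110, edgeR adjusted p = 1.14e-23). Next came MAPK8IP2 (log2 fold change 2.23), the lysophospholipid acyltransferase LPCAT2 (2.17), the transporter SLC16A6 (2.16), NDRG4 (2.10), SEL1L3 (2.00) and NGFRAP1 (1.96). The aldo-keto reductase AKR1C2 rose by 1.95 at a far higher level, from 308 ± 0.117 to 1194 ± 21.5 CPM. Reads shared with its closely related neighbours AKR1C1 and AKR1C3 make its own value uncertain. TUB (1.87), the adhesion receptor ADGRG1 (1.83), N-cadherin CDH2 (1.77) and CTDSPL (1.70) completed the 12 largest rises.

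Under the same limits the largest fall was that of CDCA7L, from 9.71 ± 0.276 to 0.576 ± 0.115 CPM (SD, n = 3 each; log2 fold change -4.06, SE 0.164, edgeR adjusted p = 1.29e-23). The actin nucleator COBL followed at -3.40, and AMOT, the angiomotin scaffold of the Hippo pathway, at -3.10. Plasminogen, PLG, fell from 9.02 ± 0.854 to 1.12 ± 0.372 CPM (SD, n = 3 each). The orphan nuclear receptor NR5A2, which drives bile acid and cholesterol genes in liver, had a log2 fold change of -2.33. MTTP, which loads lipid onto apolipoprotein B, went from 120 ± 4.83 to 28.2 ± 0.407 CPM (-2.09). The other large falls were TNNI2 (-2.78), the adhesion molecule ALCAM (-2.46), FKBP11 (-2.26), the myosin light chain MYL9 (-2.21), the progenitor marker PROM1 (-2.16) and the metalloprotease MEP1A (-2.14).

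**Figure D2:**
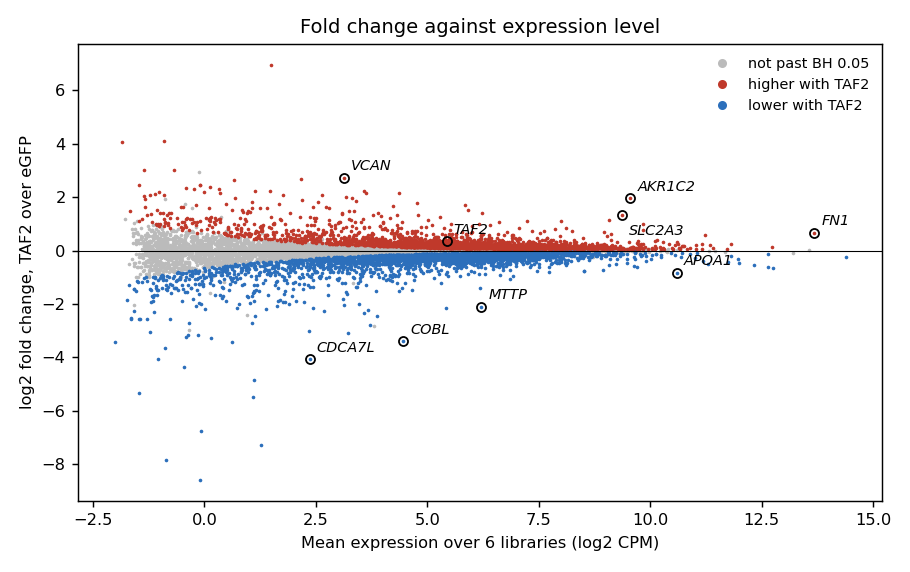
Log2 fold change of TAF2 over eGFP against mean expression (log2 CPM over 6 libraries) for the tested genes; red points rose, blue points fell and grey points were not past BH 0.05. VCAN (2.73) and CDCA7L (-4.06) lie far from 0, and TAF2 (0.36) lies among many genes of like or larger change.

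Genes of some chromosome regions moved together. Over genes of at least 5 CPM, the median log2 fold change on chromosome 11 was -0.27, and 94.6% of its 593 genes were lower with TAF2. On chromosome 4 the median was -0.18, with 89.1% of 357 genes lower. Chromosome 2 from 190 Mb onward had a median of 0.21 over 182 genes, 91.2% of them higher, against -0.05 over the 502 genes below 190 Mb. Its bin from 180 to 190 Mb, not counted as shifted, had 0.08 over 13 genes. The 190 Mb edge is thus that of a bin and not a located step. The 3 bins of chromosome 1 up to 30 Mb had medians of -0.18, -0.19 and -0.15, and the bin of chromosome X up to 10 Mb had 0.24 over 16 genes. Each of the medians of chromosomes 4 and 11 had a permutation p of 1e-04 against 10000 random gene lists (adjusted p = 0.000383), the smallest these permutations can give. The test does not single them out: 13 of 23 chromosomes passed, 6 of them at that same p, but the medians of the other 11 lay between -0.02 and 0.08. Between libraries of a group the chromosome 11 median varied with an SD of 0.00526 (eGFP) and 0.00458 (TAF2, n = 3 each). Of 272 bins of 10 Mb, 33 were shifted, 10 of them on other chromosomes than 4 and 11. Those 10 bins and the whole of chromosomes 4 and 11, called the shifted regions here, held 1681 tested genes and 1185 of the called genes, 957 of them lower. Outside them 4363 genes were called, 38.9% of those tested, and a fit without the shifted genes, chosen after seeing the data, called 4140 genes, 2005 higher and 2135 lower. For each list past the threshold, counts outside these regions are given with the totals, and members named as exceptions to a group were chosen after their values were seen.

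**Figure D3:**
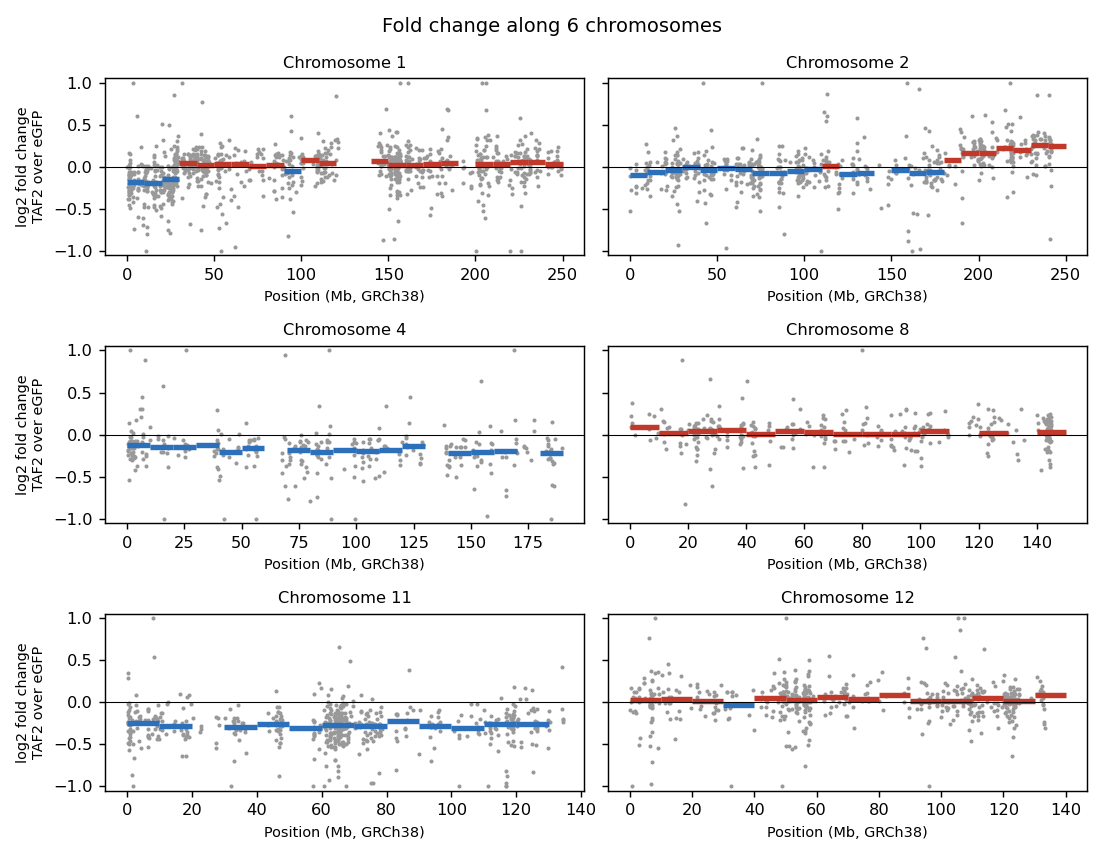
Log2 fold change of TAF2 over eGFP (vertical axis, values beyond 1 or -1 drawn at the edge) along 6 chromosomes (position in Mb, GRCh38); grey points are genes of at least 5 CPM and horizontal bars the medians of bins of 10 Mb with at least 10 genes. Chromosome 11 lies below 0 along its length (median -0.27) and chromosome 4 likewise (-0.18). Chromosome 2 lies above 0 from 190 Mb onward (0.21), with its bin from 180 to 190 Mb at 0.08.

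Of 33 measured genes for proteins that hepatocytes secrete into blood, 24 fell and 4 rose (24 and 5 adjusted over the list alone), with a median log2 fold change of -0.33. The list was lower than other genes by camera with a preset correlation of 0.01 (adjusted p = 3.07e-22), but adjusted p = 0.0558 with an estimated correlation. Albumin, ALB, went from 7766 ± 36.1 to 5069 ± 69.5 CPM (log2 fold change -0.62, SE 0.017, edgeR adjusted p = 3.6e-29), APOA1 from 1976 ± 44.1 to 1119 ± 14.5 CPM (-0.82), APOH from 1008 ± 17.3 to 654 ± 11.4 CPM (-0.62) and complement C3 from 2958 ± 56.4 to 2085 ± 23.3 CPM (-0.50; SD, n = 3 each). The members that rose were FGB (0.64), APOA2 (0.31), ITIH2 (0.08) and ORM1 (0.08, reads shared with ORM2). ALB lies on chromosome 4 and APOA1 on chromosome 11, and outside the shifted regions 18 members fell and 3 rose among 25, with a median of -0.31.

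Gluconeogenesis, urea cycle and amino acid genes fell in 13 of 21 members and rose in 1 (13 and 1 adjusted over the list alone; camera adjusted p = 2.18e-07, adjusted p = 0.104 with an estimated correlation). BHMT, which remethylates homocysteine, fell to 4.42 ± 0.726 CPM (log2 fold change -2.01), and MAT1A, the liver enzyme that makes S-adenosylmethionine, had -0.97. GLUD1 (-0.44) and pyruvate carboxylase PC (-0.49, on chromosome 11) also fell. The urea cycle enzyme CPS1 (0.17), in the raised part of chromosome 2, rose. Outside the shifted regions 11 members fell and 0 rose among 18. Liver transcription factors went both ways (9 fell and 4 rose of 23, also adjusted over the list alone; camera adjusted p = 0.422). Within it NR5A2 fell, PPARA fell by 0.47, and CEBPB (0.32) rose.

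Cholesterol synthesis enzymes fell in 17 of 25 members and rose in 1 (17 and 1 adjusted over the list alone), with camera adjusted p = 5.39e-07 and adjusted p = 0.246 with an estimated correlation. TM7SF2 (log2 fold change -0.76) and DHCR7 (-0.62) are on chromosome 11 and MSMO1 (-0.66) on chromosome 4, while EBP (-0.61) is on the X chromosome. Outside the shifted regions 13 of 21 fell and 1 rose. In fatty acid and triglyceride synthesis 15 of 20 fell and 2 rose (15 and 2 adjusted over the list alone; camera adjusted p = 8.59e-05, adjusted p = 0.246 with an estimated correlation). The acyltransferase AGPAT2 (-1.38) was its strongest faller among the named genes, with the desaturases FADS2 (-0.52) and FADS1 (-0.47) and the triglyceride enzyme DGAT2 (-0.46), these last on chromosome 11. AGPAT2 (chromosome 9, 136673143 to 136687457) lies beside EGFL7 (136658856 to 136672678), which also fell (-1.52). The pair may not have moved independently. ELOVL5 (0.09) and ACSL3 (0.20) rose. Outside the shifted regions 12 of 15 fell and 1 rose.

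Fatty acid oxidation and ketone synthesis genes fell in 17 of 22 members and rose in 2 (19 and 2 adjusted over the list alone; camera adjusted p = 0.000323, adjusted p = 0.384 with an estimated correlation). HADH (-0.51) and PPARA (-0.47) fell, whereas CPT1A, the gatekeeper of fatty acid entry into mitochondria, rose by 0.49 although it lies on chromosome 11. ETFB (0.27) also rose. Outside the shifted regions 14 of 18 fell and 1 rose. Bile acid and drug metabolism genes went both ways, with 9 lower and 7 higher of 20 (9 and 7 adjusted over the list alone; camera adjusted p = 0.497). SULT2A1 (-0.60), FMO5 (-0.87) and UGT2B7 (-0.61) fell and ALDH1A1 (0.22) rose.

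The glycolysis and hypoxia list did not pass the threshold (15 fell and 5 rose of 33, 17 and 5 adjusted over the list alone; camera adjusted p = 0.743). The glucose transporter SLC2A3 rose from 378 ± 15.4 to 942 ± 12.7 CPM (log2 fold change 1.32) and SLC2A1 from 682 ± 20.5 to 1163 ± 28.6 CPM (0.77; SD, n = 3 each), while VEGFA (-0.27) and BNIP3 (-0.24) fell. Nuclear-encoded oxidative phosphorylation genes were mostly not called (13 fell and 7 rose of 52, the same counts adjusted over the list alone; camera adjusted p = 0.422). The named members NDUFS8 (-0.43), SDHD (-0.42), NDUFC2 (-0.26) and COX8A (-0.30) all lie on chromosome 11, and outside the shifted regions 6 fell and 5 rose of 43. Genes of the mitochondrial genome were not analysed here.

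The NRF2 antioxidant list had the largest rise of the lists past the threshold. Of its 21 members 16 rose and 1 fell (16 and 1 adjusted over the list alone), with a median log2 fold change of 0.28, camera adjusted p = 7.47e-30 and adjusted p = 0.0546 with an estimated correlation. AKR1C2 (1.95), AKR1C3 (1.13) and AKR1C1 (0.60) are closely related neighbours, and AKR1C1 reached 2884 ± 34.5 CPM. Thioredoxin reductase TXNRD1 rose by 0.53, from 430 ± 7.94 to 623 ± 11.4 CPM (SD, n = 3 each). Without the 3 AKR1C genes, a choice made after seeing the data, the other 18 members had a median of 0.24 (camera adjusted p = 2.89e-10, adjusted p = 0.102 with an estimated correlation). PGD (-0.11), on chromosome 1, fell. Outside the shifted regions 15 of 17 rose and 0 fell.

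Heat shock genes rose in 13 of 18 members and fell in 3, also adjusted over the list alone (camera adjusted p = 7e-06, adjusted p = 0.246 with an estimated correlation). HSPA1A (0.41, reads shared with HSPA1B), HSP90AB1 (0.24), HSPE1 (0.30) and HSPD1 (0.25) rose, the last pair lying in the raised part of chromosome 2. The 3 that fell, HSPA4L (-0.23), STIP1 (-0.13) and CHORDC1 (-0.09), lie on chromosomes 4 and 11, and outside the shifted regions 11 of 11 rose. Targets of ATF4 in the integrated stress response rose in 20 of 30 members and fell in 3, also adjusted over the list alone (camera adjusted p = 0.00101, adjusted p = 0.49 with an estimated correlation). ATF4 (0.20), the amino acid transporter SLC7A5 (0.29) and PPP1R15A (0.32) rose, CTH (-0.16), CARS (-0.11) and AARS (-0.06) fell, and outside the shifted regions 17 of 26 rose and 2 fell. Chaperones of the endoplasmic reticulum went both ways (10 fell and 5 rose of 24, 10 and 6 adjusted over the list alone; camera adjusted p = 0.497), with SYVN1 (-0.29) and HYOU1 (-0.18) lower and DNAJB11 (0.22) higher. For p53 targets 9 of 27 rose and 6 fell (10 and 7 adjusted over the list alone; camera adjusted p = 0.497), among them AEN (0.18), FDXR (0.18), DDB2 (-0.49) and TP53I3 (-0.35).

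MYC targets and ribosome biogenesis genes rose by small amounts in 22 of 33 members and fell in 2, also adjusted over the list alone (camera adjusted p = 0.000386, adjusted p = 0.216 with an estimated correlation). Nucleolin, NCL, rose by 0.33, from 1370 ± 19.1 to 1717 ± 3.08 CPM, and NPM1 (0.20), NOLC1 (0.25) and ODC1 (0.17) also rose. MRTO4 (-0.23) and LYAR (-0.11) fell. NCL lies in the raised part of chromosome 2, and outside the shifted regions 19 of 27 rose and 0 fell. Cytosolic ribosomal protein genes rose in 39 of 75 and fell in 11 (40 and 11 adjusted over the list alone; camera adjusted p = 0.159). Their falls, such as RPS13 (-0.24) and FAU (-0.24) on chromosome 11 and RPL11 (-0.22) on chromosome 1, all lay in the shifted regions, where 1 member, RPL37A (0.31), rose. Outside them 38 of 63 rose and 0 fell.

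DNA replication genes rose in 19 of 41 members and fell in 5 (20 and 5 adjusted over the list alone; camera adjusted p = 0.0762), with MCM5 (0.24), PCNA (0.18) and MCM7 (0.14) higher and FEN1 (-0.25, on chromosome 11) lower, and outside the shifted regions 19 of 36 rose and 2 fell. Mitosis genes rose in 22 of 40 and fell in 3 (23 and 3 adjusted over the list alone). TPX2 (0.20), BUB1B (0.19) and CCNB1 (0.15) rose, but UBE2C, which loads ubiquitin onto mitotic cyclins, fell from 28.05 ± 0.853 to 12.04 ± 0.955 CPM (-1.22; SD, n = 3 each), with CCNA2 (-0.11) and MAD2L1 (-0.09) on chromosome 4. Of 37 members outside the shifted regions, 22 rose and 1 fell. The mitosis list was just past the threshold (camera adjusted p = 0.0482, adjusted p = 0.571 with an estimated correlation). It was not past it without the shifted regions (adjusted p = 0.054), with at least 1 CPM required (0.0599), or without eGFP replicate 1 (0.0567), eGFP replicate 3 (0.061), TAF2 replicate 1 (0.103) or TAF2 replicate 3 (0.0506), and over the alternatives its camera adjusted p ran from 0.00117 to 0.571. Replication-dependent histones had 8 tested members, of which HIST1H2BK fell (-3.23, at 1.35 CPM in eGFP) and none rose (the same adjusted over the list alone; camera adjusted p = 0.729).

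Immediate early and ERK-responsive genes rose in 11 of 25 members and fell in 1 (12 and 1 adjusted over the list alone; camera adjusted p = 0.000386, adjusted p = 0.153 with an estimated correlation). The feedback phosphatases DUSP5 (1.13) and DUSP6 (0.29), the feedback inhibitor SPRY4 (0.59) and JUN (0.32) rose, JUND (-0.11) fell, and outside the shifted regions 11 of 23 rose and 1 fell. YAP and TEAD targets rose in 11 of 18 and fell in 2 (11 and 3 adjusted over the list alone; camera adjusted p = 0.00337, adjusted p = 0.158 with an estimated correlation). AJUBA (0.48), AMOTL2 (0.67) and the growth factor AREG (1.01, from 1.95 to 3.93 CPM) were among the rises, ARHGEF17 (-0.27) and FJX1 (-0.25) on chromosome 11 fell, and outside the shifted regions 10 of 15 rose and 0 fell.

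Wnt and beta-catenin targets rose in 9 of 19 and fell in 5 (9 and 6 adjusted over the list alone; camera adjusted p = 0.0268, adjusted p = 0.396 with an estimated correlation). BMP4 (0.71), NOTUM (0.39), LGR5 (0.32) and TNFRSF19 (0.31) rose, DKK4 (-0.84), SLC1A2 (-0.25), GLUL (-0.19), RHBG (-0.18) and DKK1 (-0.09) fell, and outside the shifted regions 8 of 16 rose and 4 fell. This list was not past the threshold without eGFP replicate 2 (adjusted p = 0.056) or with limma-voom (0.135), and its camera adjusted p ran from 0.0127 to 0.396 over the alternatives. TGF-beta and BMP targets went both ways (7 rose and 6 fell of 20, also adjusted over the list alone; camera adjusted p = 0.497), with THBS1 (0.72) and TGFBI (0.26) higher and HAMP (-0.66) lower.

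Fibronectin, FN1, one of the most abundant transcripts, rose from 10058 ± 235 to 16024 ± 156 CPM (log2 fold change 0.67, SE 0.017; SD, n = 3 each) and lies in the raised part of chromosome 2. The mesenchymal and matrix list that holds it was mixed (10 rose and 6 fell of 26, 11 and 6 adjusted over the list alone; camera adjusted p = 0.484), since CDH2 rose while MYL9 and TAGLN (-0.88, on chromosome 11) fell. Epithelial junction genes were mixed too (9 rose and 7 fell of 26, the same adjusted over the list alone; camera adjusted p = 0.569), with KRT8 (0.25), KRT18 (0.24) and CLDN4 (0.45) higher and the tight junction scaffold TJP3 lower (-1.55). Bile duct markers rose in 4 of 8 and fell in 3, also adjusted over the list alone (camera adjusted p = 1.05e-05, adjusted p = 0.102 with an estimated correlation). SPP1 went from 336 ± 6.45 to 739 ± 6.86 CPM (1.14, on chromosome 4), CLDN4 rose by 0.45 and KRT19 by 0.32, while ANXA4 (-0.18), EPCAM (-0.15) and SOX9 (-0.07) fell. Of 6 members outside the shifted regions, 3 rose and 3 fell. This list was not past the threshold with limma-voom (adjusted p = 0.113) or without the shifted regions (0.0749), and its camera adjusted p ran from 4.27e-09 to 0.113. Among fetal liver and liver cancer genes 10 of 20 fell and 4 rose (10 and 5 adjusted over the list alone; camera adjusted p = 0.982), with IGF2 at -0.67, PROM1 at -2.16, SPP1 at 1.14 and AKR1B10 at 0.71.

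**Figure D4:**
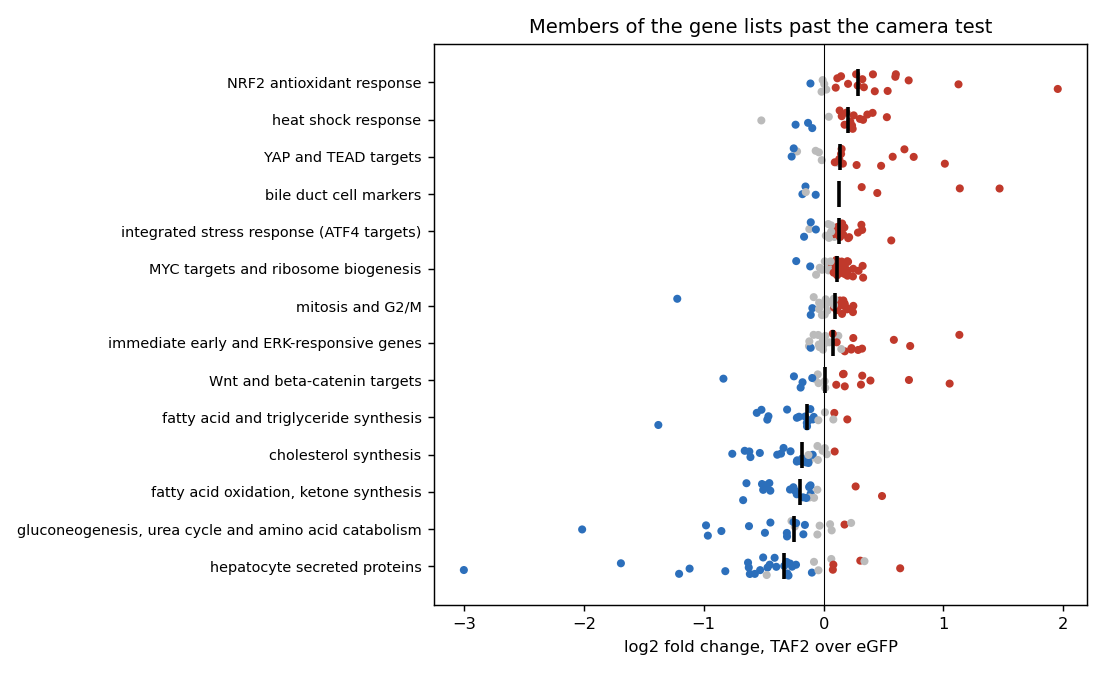
Log2 fold change of TAF2 over eGFP for the tested members (points) of the 14 lists past the camera test with a preset correlation; red rose, blue fell, grey was not past BH 0.05, and the black bar is the list median. Medians run from -0.33 for hepatocyte secreted proteins to 0.28 for the NRF2 list, and members of most lists lie on both sides of 0.

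Interferon-stimulated genes fell in 12 of 28 members and rose in 6, also adjusted over the list alone (camera adjusted p = 0.497). The sensor IFIH1 (-0.55) and PARP9 (-0.66) fell, whereas IFITM3 (0.35) and IFITM2 (0.30) rose. MHC class I genes fell in 9 of 15 and rose in 1 (10 and 1 adjusted over the list alone), TAP2 (0.10), with HLA-E (-0.29), ERAP1 (-0.35), ERAP2 (-0.34) and PSMB9 (-0.71) lower, yet the list missed the threshold (camera adjusted p = 0.0523). None of its members lay in the shifted regions. NF-kB and inflammatory genes fell in 7 of 15 and rose in 2 (9 and 2 adjusted over the list alone; camera adjusted p = 0.286), with ICAM1 (-0.44), BIRC3 (-1.64) and NFKB1 (-0.27) lower and CCL20 (0.16) higher. Apoptosis regulators fell in 6 of 25 and rose in 3, also adjusted over the list alone (camera adjusted p = 0.644). BIRC2 (-0.43) and BIRC3 on chromosome 11 fell, and BCL2L1 rose (0.21). Autophagy and lysosome genes rose in 12 of 31 and fell in 6, also adjusted over the list alone (camera adjusted p = 0.497), with WIPI1 (0.59) and CTSL (0.41) higher and CTSD (-0.50) and NEU1 (-0.21) lower.

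The other subunits of TFIID went both ways by small amounts. Of 17 tested, 5 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.497). TAF9B (0.27), TAF15 (0.21), TAF4 (0.21), TAF1 (0.13) and TAF7 (0.09) rose, while TAF9 (-0.16), TAF11 (-0.14) and TAF10 (-0.32, on chromosome 11) fell. General transcription factor and RNA polymerase II genes were split (6 rose and 6 fell of 29, also adjusted over the list alone; camera adjusted p = 0.844), and POLR2G (-0.36), POLR2L (-0.25) and GTF2H1 (-0.31), all on chromosome 11, were lower while GTF2F2 (0.27) was higher. Mediator subunits were split likewise (6 rose and 6 fell of 31, also adjusted over the list alone; camera adjusted p = 0.743), with MED15 (0.15) and MED9 (0.23) higher and MED28 (-0.22) and MED20 (-0.20) lower. Neighbours of TAF2 in band 8q24 rose in 6 of 19 and fell in 2 (6 and 3 adjusted over the list alone; camera adjusted p = 0.658), among them MYC (0.18), KIAA0196 (0.30), EXT1 (0.20), ZHX2 (-0.22) and ENPP2 (-0.92).

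Markers of other cell types gave no common direction. Fibroblast and stellate markers had 6 tested members, 2 higher and 2 lower (also adjusted over the list alone; camera adjusted p = 0.671), with PDGFRB (1.32) and COL1A1 (1.13, from 0.67 to 1.51 CPM) higher and TAGLN and FBLN1 (-0.15) lower. COL1A2 and COL3A1 never exceeded 0.0392 CPM in a library. Endothelial markers were too few to test as a list (4 tested, 1 rose and 1 fell, also adjusted over the list alone), with ROBO4 at 3.17 CPM and EGFL7 at 1.13 CPM with TAF2. Of 9 blood and immune markers 1 rose and 3 fell (1 and 4 adjusted over the list alone; camera adjusted p = 0.566), LYZ by 0.22 upward and CD68 (-0.40), CD74 (-0.23) and CD14 (-1.01) downward. Markers of embryonic kidney lines fell in 1 of 5, SALL2 (-0.90), and rose in 0, also adjusted over the list alone (camera adjusted p = 0.363). Housekeeping reference genes stayed close to 0, with 8 higher and 3 lower of 26, also adjusted over the list alone (camera adjusted p = 0.743), such as TFRC (-0.08) and C1orf43 (-0.14).

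Of 40 lists tested, 14 were past the threshold by camera with the preset correlation, 9 higher and 5 lower. With an estimated correlation 0 of these held. For bile duct markers the estimated correlation was -0.00695, under the preset 0.01, yet the camera p went from 1.57e-06 to 0.00766. For YAP and TEAD targets it was -0.00424, and the camera p went from 0.00101 to 0.0237. The other lists past the threshold had estimated correlations above the preset. Since camera with an estimated correlation also uses fewer degrees of freedom, the loss cannot be put down to correlation between genes alone. By fry, which asks whether a set moves on balance in one direction and does not compare it with other genes, 30 lists passed. The list median, mean and camera direction differed in sign for the 8q24 neighbours (median -0.01, mean -0.04, camera upward), the fetal liver list (-0.05, -0.11, camera upward) and the epithelial junction list (0.01, -0.20, camera upward).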

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

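The fits without the shifted regions, with GC and length corrected, and of the NRF2 list without AKR1C genes were chosen after seeing the data. The number of genes past the threshold stayed between 4079 (DESeq2) and 5732 (no filter on low counts) except under glmTreat, and ranged from 4800 to 5288 when a library was left out. Against 1.5-fold, glmTreat called 373 genes, 153 higher and 220 lower, and did not call TAF2 (log2 fold change 0.36, adjusted p = 1), since it asks for a larger change. Under each setting that tested genes, the genes called there and in the reported fit had the same sign. Of 169 named genes, 51 stayed called under glmTreat, and under the other settings those tested kept their direction and their call. Lists past the threshold numbered 13 to 17 under the gene-level alternatives, 0 with an estimated correlation and 30 by fry. The fetal liver list was downward by fry (median -0.0528, adjusted p = 0.0238, against up to 0.998 over its alternatives) and upward, not past the threshold, by camera; the cause was not tested. Ribosomal protein, DNA replication and MHC class I lists passed with no filter, with limma-voom and without the shifted regions. The ribosomal list also passed with DESeq2, with GC and length corrected and without eGFP replicate 1, the MHC list without eGFP replicate 3 or TAF2 replicate 3, and the DNA replication and MHC lists by fry. Calls were more often lower than higher except with upper-quartile scaling (3001 higher, 2675 lower), GC and length corrected (2957, 2726) and no filter (2958, 2774). Deviations of same-numbered libraries from their group means correlated at -0.0446, -0.0905 and -0.103, so no shared effect of a replicate number was seen. Whether same-numbered libraries were made together is not stated in the labels. With the replicate number as a block, 5250 genes were called and the mitosis list had adjusted p = 0.0542. At the observed depth and replicate number, 32.0% of genes changed by 1.1-fold were called in simulated counts, where far fewer genes changed than were called in the data. Depth itself was not varied.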

Other observations

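Members of 3 gene families moved in a single direction each, and those of another family in both. The families were chosen after their values were seen and not tested as sets. All the metallothioneins counted here lie on chromosome 16, and the clade A serpins on chromosome 14 except SERPINA7 on the X chromosome. Members on the same chromosome may not have moved independently. All 7 metallothioneins with a mean of at least 1 CPM fell, from -0.30 for MT1X and MT1E to -0.88 for MT1G, -1.10 for MT1F, -1.87 for MT1A and -3.44 for MT1M. MT2A, the most abundant of them, went from 284 ± 0.389 to 225 ± 9.13 CPM (SD, n = 3 each; edgeR adjusted p = 1.14e-14), and reads shared within this family make single members uncertain. All 5 IGF-binding protein genes measured at that level rose. IGFBP1, a secreted liver protein that binds insulin-like growth factors, went from 605 ± 23.9 to 1218 ± 47.0 CPM (log2 fold change 1.01, adjusted p = 3.41e-10), with IGFBP3 at 1.254, IGFBP2 at 0.51, IGFBP4 at 0.43 and IGFBP6 at 0.38; IGFBP2 lies in the raised part of chromosome 2. All 8 clade A serpins at that level fell, SERPINA1, which encodes alpha-1-antitrypsin, by 0.31 from 4415 ± 59.5 CPM and SERPINA6, the corticosteroid-binding globulin, by 0.74. Of 11 such facilitative glucose transporters, 2 of them named above among the glycolysis genes, 3 rose and 3 fell: SLC2A3 (1.32), SLC2A1 (0.77) and SLC2A8 (0.12) were higher and SLC2A2 (-0.93), the main glucose transporter of hepatocytes, SLC2A13 (-0.33) and SLC2A4 (-0.25) were lower. These counts were the same under the 4 other scalings tried.

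A few genes were close to absent in one group. With a group mean under 0.2 CPM on one side and at least 1.5 CPM on the other, a rule set after seeing the data, 7 genes were found, 6 of them near 0 with TAF2. DPP10 had 352 counts over the 3 eGFP libraries and 2 over the 3 TAF2 libraries, and the overlapping DPP10-AS1 had 142 and 1, which cannot be separated without strand. MYRIP had 313 and 7 counts, ARHGAP10 (on chromosome 4) 310 and 11, LACTBL1 (in the lowered start of chromosome 1) 122 and 14, and RAB34 141 and 0. SLC6A2, the noradrenaline transporter (chromosome 16, 55655988 to 55706192), went the other way with 3 and 441 counts, or 0.0407 ± 0.00408 and 5.63 ± 0.314 CPM (SD, n = 3 each). LPCAT2 (55509072 to 55586666), ADGRG1 and NDRG4, among the 12 largest rises, also lie on chromosome 16 between 50 and 60 Mb. That bin had a median log2 fold change of 0.03 and was not shifted. Whether these neighbouring rises share a cause was not tested.

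Among the tests below, those on expression level in the shifted regions and on GC content for chromosomes 4 and 2 were set down before their results were seen, and the others after. The shifts of whole chromosome regions were compared with GC content and transcript length as a technical cause. After correction for both, the median log2 fold change stayed at -0.25 on chromosome 11, -0.16 on chromosome 4 and 0.22 on chromosome 2 from 190 Mb, which argues against that bias as the whole cause. A candidate explanation is a copy-number difference between the 2 cell populations, which would move strongly and weakly expressed genes alike. The medians of the more and the less expressed genes of each region, parted at its median CPM, differed by 0.0215 on chromosome 11, 0.0315 on chromosome 4 and 0.0066 on chromosome 2 from 190 Mb, as that hypothesis needs. An even shift of a region from any other cause would give the same, so this does not favour copy number. An effect of TAF2 on these regions stays open and untested, since DNA copy number was not analysed here.

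TAF2 rose by 1.28-fold, less than 596 other genes that rose. A gain of the region around it would raise its neighbours too, but the 29 genes of at least 5 CPM within 10 Mb had a median log2 fold change of 0.0741 (SD 0.137), below the 0.36 of TAF2 by more than their spread. A library swapped between the groups is argued against by the TAF2 level itself, since the lowest TAF2 library stood at 1.17 times the highest eGFP library. Whether reads of an introduced TAF2 copy were fully counted in this row was not tested and stays open.

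The number of called genes, 5548, was set against the other ways of splitting the libraries. Of the 10 splits into 3 and 3, only 1, the real one, gave as many, the highest of the others gave 0, and 10 splits are too few for a share under 0.05. Each other split puts libraries of both groups on each side. The group difference then widens the spread within a side, so 0 calls there say little. The shifted regions alone do not account for the calls, since 38.9% of tested genes outside them were called. Nor does GC content or transcript length, since 95.8% of the calls remained after correction. Differences that arose between the 2 cell populations apart from TAF2, such as selection of cells during their making, coincide with the groups and were not tested.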
